A study of Mus musculus with 8 samples.

How the data were processed

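Total RNA from the liver of KKAy and C57BL/6J mice at 4 and 11 weeks of age was measured on 8 one-colour Agilent arrays, 2 in each of 4 groups. Strain, age and replicate number came from the labels. Per the labels' protocols, the mice ate standard chow and were fasted overnight, RNA was prepared on RNeasy columns, and cRNA was labelled with Cy3. The sex of the mice is not given in the sources used here. Each array held 43379 spots for 41174 probes and 1639 control spots, and 245 probes were spotted 10 times. Each slide held 4 arrays: slide 1 held the 4-week groups and slide 2 the 11-week groups, with C57BL/6J at positions 1 and 2 and KKAy at positions 3 and 4 on both, so strain goes with position on the slide.

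Per the file headers, spot intensity was extracted with Agilent Feature Extraction 9.5.1.1, which subtracted background, removed trends across the array and put surrogate values in place of the dimmest signals; no normalization between arrays was applied to these values. The deposited value table holds log2 values: per array it equals the log2 processed signal minus 1 constant, within 0.001 for 99.4% of probes, with the 75th percentile at 0. Its column medians lay between -3.96 and -3.67, no centring across arrays was found, and the tool that made the shift is not given in the sources used here. No column of that table belonged to no sample (0 such columns), and it served as an alternative source of values.

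For the main analysis, repeated spots of a probe were averaged, control spots and spots flagged as non-uniform or population outliers were left out (59 to 89 per array), and log2 processed signal was taken relative to each array's 75th percentile. No spot was saturated (0 on each array). Negative controls had a median signal of 50 to 57.0 units. Probes well above background on both arrays of at least 1 group were kept (25318 probes), and a gene was represented by its brightest probe, which gave 17049 genes, 14420 of them with a gene name. Names came from a reference table of the assembly GRCm38.p6, matched by accession (24375 probes), symbol (6301) or older symbol (2426); 8072 probes kept the name in the files. Positions of probes are those of the file annotation, on mm8. The second probe of Socs2 went the other way from the brightest one, and those of Cap2, Cyp2c38, Igf2bp3 and Sult2a2 went the same way by less, as given beside their values. Members of multigene families, for the paralog tests, were told by the first letters of gene names, in a wider and a narrower form.

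Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 arrays, so that the groups shared 1 estimate of the spread, with 4 residual and 1.926 prior degrees of freedom. Contrasts were KKAy minus C57BL/6J at each age, 11 minus 4 weeks in each strain, and the difference of those differences (the interaction). P-values were adjusted by Benjamini-Hochberg over the genes tested, at 0.05. Counts of list members given as higher, lower, above 0 or below 0 are of members past that threshold. Members not counted may lie on either side of 0. Where a gene was not well above background on either array of a group, its fold change is given as a bound: the mean of the brighter group against, per array of the dimmer group, the higher of its own signal and the lowest signal among probes well above background. These bounds hold for the processed signal; the offset of normexp is added to all signals and draws dim ones together. A total of 32 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation (statmod 1.5.0 installed) and with fry, adjusted over the lists within a comparison; 10 genes with a flagged spot were left out of set tests, and the agouti list, with 2 members, had no set test. The lists, the tests, the alternatives and the genes to name were fixed before the data were examined, except where a choice is said to have come later. Genes named in each comparison were the 6 largest rises and 6 largest falls among named genes past the threshold and well above background on both arrays of the higher group, the 2 members with the smallest adjusted p of the 8 lists with most members called, and the agouti locus; for the interaction, 4 rises, 4 falls and 4 lists. Some genes that this rule names are not reported; they count among the named genes of the comparisons and alternatives, but not in the count of named genes with an interaction. Figures were drawn with matplotlib 3.10.9, and tables prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

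The procedure was tested on simulated data for 17043 genes, with 200 genes changed per comparison besides a shifted list. Noise was drawn independently for each array, while same-numbered arrays here deviated together. Fewer genes were changed than were called in the real comparisons, so the shares below do not give the power of those. Per comparison 1 to 11 unchanged genes were called. Of genes changed by 1 on the log2 scale 17.9% to 41.8% were called over the 5 comparisons, of those changed by 2, 64.2% to 83.6%, and of those changed by 3, 72.7% to 93.9%; the lowest share was that of the interaction each time. Alternatives were normexp background correction (offset 50), quantile normalization, the median of detected probes or the deposited value table, no filter or a filter on all 8 arrays, flagged spots kept, the mean of a gene's probes, only the 4 arrays of a comparison, an intensity trend with robust variance, the replicate number as a block, and leaving out each array. Cyclic loess and scaling to 7 spike-in probes were added after the data were seen.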

Results

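Liver RNA of 2 mouse strains was compared at 2 ages on 8 one-colour arrays, with 2 arrays in each of 4 groups: C57BL/6J at 4 weeks, C57BL/6J at 11 weeks, KKAy at 4 weeks and KKAy at 11 weeks. KKAy is an obese, diabetes-prone strain that carries the yellow allele of the agouti gene, and the labels name its state as diabetes and that of C57BL/6J, a standard inbred strain, as normal. All mice ate chow and were fasted overnight before sampling. By its title, the series concerns expression signatures of diabetic and of normal mouse liver. The 75th percentile of processed signal lay between 491.6 and 1241 fluorescence units per array, and 56.3% to 66.7% of spots were well above background. After filtering, 17049 genes were tested, and the median SD between the 2 arrays of a group ran from 0.126 to 0.222 on the log2 scale. The labels number the samples but do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. Fold changes below are log2 differences of group means with their SE, from 2 arrays per group, and the number of arrays limits their precision. Same-numbered arrays of the groups deviated together, and the estimated inter-gene correlation used below came from residuals that hold these deviations. Counts and calls that change with the replicate number as a block are given with the other processing alternatives near the end.

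At 4 weeks, KKAy livers had far more transcript of a few genes that were nearly silent in C57BL/6J. By camera, acute phase genes were shifted up in KKAy, and genes of the interferon response, antigen presentation, macrophages and lymphocytes down. None of these 5 lists was called with an estimated correlation (adjusted p = 0.0682 to 0.25). The agouti gene a, which encodes a secreted blocker of melanocortin receptors and whose probe lies on chromosome 2 at 154737198 to 154739151 (mm8), was not well above background in C57BL/6J and was at least 494-fold higher in KKAy (adjusted p = 0.000114). Raly, its neighbour at 154558570 to 154558629 and an RNA-binding protein gene, was lower in KKAy by a log2 change of -0.86 (SE 0.14, adjusted p = 0.0105). Cdh15, which encodes M-cadherin, was higher by 9.05 (SE 0.16), and Ifi202b and Serpina3a were at least 51.3-fold and 62.7-fold higher. Cap2 was at least 37.8-fold higher on its brightest probe and higher by 4.82 on its second. Gdpd3, a glycerophosphodiester phosphodiesterase gene measured on 1 of the 2 C57BL/6J arrays, was higher by 7.63 (SE 0.65). In the opposite direction, Thumpd1, Zfp874a, Camk2b, Adgrf1, Lncbate1 and Ear10 were not well above background in KKAy and were at least 149-fold, 81.6-fold, 44.3-fold, 22.3-fold, 20.4-fold and 19.1-fold higher in C57BL/6J. Ear10 belongs to a family of near-identical ribonuclease genes, so its probe may not read 1 gene alone. Each fold given as "at least" is a bound for the processed signal only. With normexp and its offset of 50, all 11 genes so bounded at this age lay below their bounds, at 4.31-fold to 112-fold (a highest, Gzma lowest), and all stayed called in the same direction. Gdpd3 came to 4.84 with normexp.

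Of 27 acute phase genes measured, 13 were higher in KKAy and 1 was lower (17 and 1 adjusted over the list alone), and camera placed the list above other genes (adjusted p = 1.21e-08). With an estimated correlation that call was lost (adjusted p = 0.246). Orm3, a plasma carrier protein gene, was higher by 2.74 (SE 0.11) and Apcs, which encodes serum amyloid P, by 2.55 (SE 0.19). Of 33 interferon response genes, 21 were lower and none was higher (23 adjusted over the list alone), with a median of -1.16 and a camera adjusted p of 1.8e-13, against adjusted p = 0.0682 with an estimated correlation. Irf7, a transcription factor of the response, fell by 3.11 (SE 0.12) and Oasl2 by 2.15 (SE 0.10). Of 19 MHC genes 12 were lower (14 adjusted over the list alone), among them the class II genes H2-Ab1, by -1.96 (SE 0.10), and H2-Eb1, by -1.74 (SE 0.10). The camera adjusted p was 1.69e-09, and adjusted p = 0.25 with an estimated correlation. Of 26 Kupffer cell and macrophage markers 16 were lower (18 lower and 2 higher adjusted over the list alone), such as Mpeg1, a pore protein of macrophages, by -1.46 (SE 0.11), and Clec4f, a lectin of Kupffer cells, by -1.35 (SE 0.12). Of 22 lymphocyte markers 13 were lower (15 adjusted over the list alone): granzyme gene Gzma was at least 17.2-fold lower and Gzmb lower by -1.96 (SE 0.10). Camera called both marker lists (adjusted p = 1.85e-07 and 1.69e-09), but with an estimated correlation neither was called (adjusted p = 0.0682 and 0.25). Erythroid markers were higher in 4 and lower in 1 of 10 (the same counts adjusted over the list alone), with camera adjusted p = 0.0307, and adjusted p = 0.527 with an estimated correlation. The call was also lost on probes above background on all arrays (adjusted p = 0.153) and with spike-in scaling (adjusted p = 0.0693).

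Other named genes came from lists that camera did not call. Among 28 female-biased liver genes, 8 were higher and 4 lower in KKAy (13 and 4 adjusted over the list alone; camera adjusted p = 0.0558). A1bg was higher by 2.38 (SE 0.13), and Cyp17a1, a steroid hydroxylase, was lower by -2.82 (SE 0.20). Among 47 xenobiotic metabolism genes, 7 were higher and 4 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.0725). Cyp2c38 was higher by 5.58 (SE 0.22) on its brightest probe and by 1.88 on its second probe, and Cyp1b1 by 2.17 (SE 0.14; 1.32 with normexp). Of 21 circadian clock genes 7 were higher and 3 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.16), among them Per3, by 2.05 (SE 0.19; 1.29 with normexp). In all, 2626 genes passed an adjusted p of 0.05 in limma, 1092 higher and 1534 lower in KKAy, and 1373 of them differed at least 2-fold. That count came to 1362 or 1317 without C57BL/6J replicate 1 or 2 of this age, 1464 or 1389 without KKAy replicate 1 or 2, 1505 with no filter on dim probes and 1405 from the 4 arrays alone. The Raly call was lost without C57BL/6J replicate 2 (adjusted p = 0.0663), without KKAy replicate 1 (adjusted p = 0.0596), from the 4 arrays alone (adjusted p = 0.068) and with spike-in scaling (adjusted p = 0.0893). Scaling to the spike-in controls, chosen after seeing the data, moved the median of all genes from 0.01 to 0.36 and the share of higher calls from 41.6% to 75.8%.

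At 11 weeks the strains differed again in a, Cdh15 and Thumpd1, and camera also called metabolic groups. Lists of fatty acid oxidation, gluconeogenesis and female-biased genes were shifted down in KKAy, and those of cholesterol synthesis, male-biased, endoplasmic reticulum stress and acute phase genes up. None of these 7 lists was called with an estimated correlation (adjusted p = 0.2 to 0.362). The agouti gene a was at least 389-fold higher in KKAy (adjusted p = 9.29e-05), and Raly was lower by -1.39 (SE 0.14, adjusted p = 0.00158). Akr1c18, a hydroxysteroid dehydrogenase gene on chromosome 13, was higher by 10.36 (SE 0.20), and Cdh15 by 7.59 (SE 0.16). Gdpd3, Serpina3a and Ifi202b were at least 143-fold, 74.9-fold and 34.8-fold higher. Thumpd1, Zfp874a, Hnf4aos, Camk2b, Olig1 and Raet1e were not well above background in KKAy and were at least 142-fold, 88.2-fold, 66.9-fold, 44.3-fold, 29.5-fold and 28-fold higher in C57BL/6J. With normexp all 10 bounded genes lay below their bounds, at 6.69-fold to 68.7-fold, and all stayed called in the same direction.

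Of 35 genes of fatty acid oxidation and PPAR alpha targets, 11 were lower and 1 was higher (the same counts adjusted over the list alone). Ehhadh, a peroxisomal oxidation enzyme, was lower by -2.24 (SE 0.13), and Acot2, an acyl-CoA thioesterase of the mitochondrion, by -1.38 (SE 0.11). Of 12 gluconeogenesis genes 4 were lower (7 adjusted over the list alone), and of 25 genes of cholesterol synthesis and uptake 11 were higher and none lower (12 and 1 adjusted over the list alone). Camera called these lists with adjusted p = 0.00871, 0.0103 and 0.000523 in that order, and with an estimated correlation none was called (adjusted p = 0.29, 0.29 and 0.362). Of 26 endoplasmic reticulum stress genes 12 were higher and none lower (15 adjusted over the list alone; camera adjusted p = 1.58e-06). Sdf2l1 was higher by 1.53 (SE 0.10) and Derl3, a component of protein degradation from the endoplasmic reticulum, by 1.70 (SE 0.13). Of 27 acute phase genes 15 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 9.7e-07), with Apcs higher by 4.07 (SE 0.19) and Orm3 by 2.26 (SE 0.11). With an estimated correlation, adjusted p = 0.2 for endoplasmic reticulum stress and adjusted p = 0.254 for the acute phase.

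Of 26 male-biased liver genes 10 were higher in KKAy and 1 lower, and of 28 female-biased genes 14 were lower and 4 higher (10 and 1, and 14 and 6, adjusted over the list alone). Camera called both (adjusted p = 0.000206 and 0.0126), and neither was called with an estimated correlation (adjusted p = 0.29 and 0.254). Cyp39a1, an oxysterol hydroxylase, was lower by -5.15 (SE 0.11), and Cyp2b9, a cytochrome P450 with close paralogs, by -3.54 (SE 0.14), which leaves cross-hybridization between Cyp2b genes possible. With normexp background correction the female-biased list was not called (adjusted p = 0.101) and its median went from -1.005 to 0.05. On probes above background on all arrays it was not called either (adjusted p = 0.116, median 0.01). Igfbp2, a carrier of insulin-like growth factors, was lower by -3.03 (SE 0.10). Socs2, a brake on growth hormone signalling, was higher by 1.63 (SE 0.16) on its brightest probe but stood at -0.10 on its second. These came from a list of 27 insulin and growth hormone signalling genes, 9 higher and 4 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.143). Cyp2c38 was again higher, by 4.07 (SE 0.22) on its brightest probe and by 0.89 on its second, among 47 xenobiotic metabolism genes of which 13 were higher and 9 lower (15 and 10 adjusted over the list alone; camera adjusted p = 0.116).

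At this age 2 of 19 MHC genes were lower past the threshold (1 adjusted over the list alone, camera adjusted p = 0.232, median of all members -0.04). Of 33 interferon response genes 12 were lower and 3 higher (14 and 3 adjusted over the list alone), and Usp18, an interferon-induced protease gene, was lower by -3.36 (SE 0.10) and Ifit1 by -1.82 (SE 0.11; -1.055 with normexp). Of 26 Kupffer cell and macrophage markers 10 were lower (12 adjusted over the list alone) and of 22 lymphocyte markers 8 were lower and 1 higher (9 and 1 adjusted over the list alone). Camera called these lists with adjusted p = 0.00226, 0.000831 and 0.00191, and none was called with an estimated correlation (adjusted p = 0.29, 0.2 and 0.362). Neutrophil markers were higher in 3 of 9 (3 higher and 1 lower adjusted over the list alone) and erythroid markers in 4 of 10 (4 adjusted over the list alone), with camera adjusted p = 0.0338 and 0.00616, and adjusted p = 0.29 for both with an estimated correlation. The neutrophil call was lost without C57BL/6J replicate 2 (adjusted p = 0.0569) or KKAy replicate 1 (adjusted p = 0.122) of this age, with normexp (adjusted p = 0.0821) and with no filter (adjusted p = 0.0908). The lymphocyte call was lost with normexp (adjusted p = 0.0996). Of 26 stellate cell and fibrosis markers 11 were lower and 3 higher (11 and 4 adjusted over the list alone; camera adjusted p = 0.116), such as Dpt, by -1.34 (SE 0.10), and the gelatinase gene Mmp2, by -1.61 (SE 0.13; -0.55 with normexp). In limma, 3660 genes passed, 1697 higher and 1963 lower, 1681 of them at least 2-fold. The count came to 1474 or 1518 without C57BL/6J replicate 1 or 2 of this age, 2418 without KKAy replicate 2, 2356 with normexp, 2126 with no filter and 2121 from the 4 arrays alone. With spike-in scaling 60.7% of calls were higher in KKAy, against 46.4%, and the median of all genes was 0.14.

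Strain differences at the 2 ages went largely the same way. Of the 1701 genes called at both ages, 681 were higher in KKAy at both and 914 lower at both, where independent lists of these sizes would share 108.7 and 176.6. Another 106 went opposite ways, against 278.4. Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson r of 0.690 and a Spearman rho of 0.547. The 2 comparisons use different arrays but share 1 estimate of the spread per gene. Strain also goes with position on both slides, and a poorer match of a probe in KKAy would recur at both ages. The excess over independent lists therefore does not by itself show a repeated difference in transcript. The count of 1595 with 1 direction came to 940 or 911 without C57BL/6J replicate 1 or 2 at 4 weeks, 831 or 830 without C57BL/6J replicate 1 or 2 at 11 weeks, 999 or 975 without KKAy replicate 1 or 2 at 4 weeks, 981 with normexp and 900 with no filter.

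**Figure D1:**
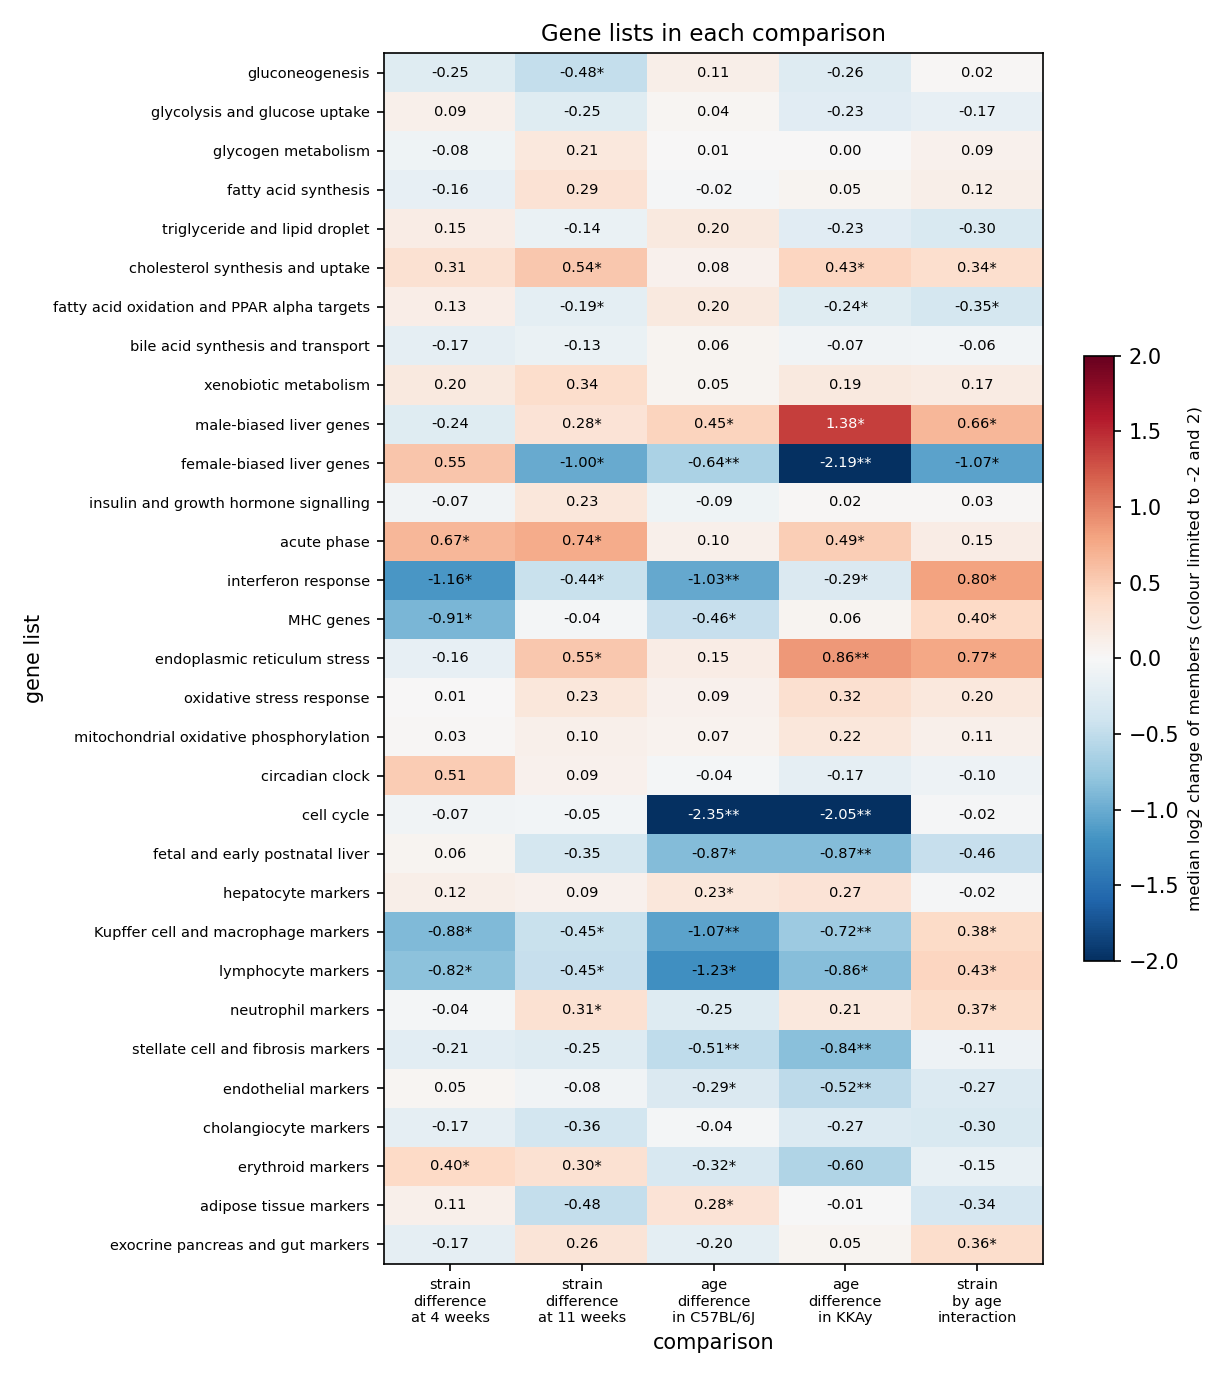
Median log2 change of the measured members of 31 gene lists (vertical axis) in the 5 comparisons (horizontal axis), as colour limited to 2 either way; strain differences are KKAy minus C57BL/6J and age differences 11 weeks minus 4 weeks. A star marks a camera adjusted p under 0.05 and 2 stars a call that also held with an estimated correlation; the cell cycle list stands at -2.35 in C57BL/6J and -2.05 in KKAy with age.

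Between 4 and 11 weeks C57BL/6J livers lost transcripts of cell division, of macrophages and the interferon response, of stellate cells, and of female-biased genes, by list calls that held with an estimated correlation. Of 26 male-biased genes 7 rose, and that list was called by camera but not with an estimated correlation (adjusted p = 0.185). All 4-week arrays lay on 1 slide and all 11-week arrays on another, so age and slide cannot be told apart in this comparison or in the next. The strain difference at 4 weeks, this comparison and the interaction share the 2 C57BL/6J arrays at 4 weeks. Their results on the same lists are therefore not independent. Of 37 cell cycle genes 24 were lower at 11 weeks (27 adjusted over the list alone), with a median of -2.35 and a camera adjusted p of 3.97e-25 that held with an estimated correlation (adjusted p = 0.0121). Ccna2, a cyclin of DNA replication, fell by 3.19 (SE 0.10), and Mki67, the proliferation marker, by 2.99 (SE 0.10). Igf2bp3, an RNA-binding protein gene of fetal tissue, was at least 42.4-fold lower on its brightest probe and lower by -5.31 and -5.38 on its other probes. It stood among 15 fetal and early postnatal genes of which 6 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.000431, and adjusted p = 0.077 with an estimated correlation).

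Of 28 female-biased genes 12 were lower and none higher (17 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.0121). Slc22a26, an organic anion transporter gene, fell by 4.96 (SE 0.26), and Hamp2, of the hepcidin family, by 2.68 (SE 0.10). Hao2, a hydroxyacid oxidase gene, was at least 10.1-fold lower. Of the male-biased genes 12 were higher and 1 lower adjusted over the list alone (camera adjusted p = 3.48e-07, and adjusted p = 0.185 with an estimated correlation). Among those past the threshold were Elovl3, a fatty acid elongase, by 2.43 (SE 0.22), and Nox4, a hydrogen peroxide-forming oxidase, by 2.36 (SE 0.13). Other rises were in Cfd, by 5.09 (SE 0.19), and Tiam2, by 4.19 (SE 0.31). Obp2a, Grid1, Rpl39l and Olfr987 were not well above background at 4 weeks and rose at least 15.6-fold, 8.59-fold, 7.06-fold and 5.58-fold, so their place among the largest rises rests on signal at the floor. With normexp these 4 came to 2.15, 1.43, 1.40 and 1.15 on the log2 scale, and all 7 genes bounded in this comparison lay below their bounds, at 2.08-fold to 8.54-fold. Cfd encodes adipsin, an adipose marker. The adipose list had 3 of 8 members higher (3 adjusted over the list alone; camera adjusted p = 0.0346, and adjusted p = 0.185 with an estimated correlation). Its call was lost without C57BL/6J replicate 2 at 4 weeks (adjusted p = 0.0759), with normexp (adjusted p = 0.404), with the mean of a gene's probes (adjusted p = 0.0659) and on probes above background on all arrays (adjusted p = 0.711), where the median turned to -0.07. The remaining large falls were in Akr1c18, by 5.08 (SE 0.20), and Slc22a29, at least 13.7-fold. The agouti gene a was below background at both ages, and Raly did not change (-0.01, SE 0.14, adjusted p = 0.974).

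Of 33 interferon response genes 18 were lower (23 adjusted over the list alone), including the chemokine Cxcl9, by -2.58 (SE 0.13), and Oas2, by -2.06 (SE 0.11). Of 19 MHC genes 7 were lower (9 adjusted over the list alone), with H2-Ab1 at -2.25 (SE 0.10) and H2-Eb1 at -2.02 (SE 0.10). Camera called both (adjusted p = 1.88e-15 and 3.32e-07). With an estimated correlation the interferon call held (adjusted p = 0.0263) and the MHC call was lost (adjusted p = 0.185). Cell type markers moved beside them. Of 26 Kupffer cell and macrophage markers 16 were lower (21 adjusted over the list alone), such as Mpeg1, by -1.22 (SE 0.11), and Laptm5, by -1.44 (SE 0.13), and that call held (adjusted p = 0.0121 with an estimated correlation). Of 22 lymphocyte markers 12 were lower (17 adjusted over the list alone), with Gzma at -3.21 (SE 0.21) and Gzmb at -2.63 (SE 0.10). Camera gave adjusted p = 3.88e-12, and adjusted p = 0.107 with an estimated correlation. Of 26 stellate cell and fibrosis markers 8 were lower (9 adjusted over the list alone), and the collagen genes Col3a1 and Col1a1 changed by -3.03 (SE 0.10) and -2.23 (SE 0.18). This call held (adjusted p = 0.0263 with an estimated correlation). Endothelial markers were lower in 1 of 20 and erythroid markers in 4 of 10 (1 and 5 adjusted over the list alone), with medians of -0.29 and -0.32, and the 19 hepatocyte markers, none of which passed by either adjustment, had a median of 0.23. Camera called these 3 lists (adjusted p = 0.00156, 0.00641 and 0.00442), and none held with an estimated correlation (adjusted p = 0.085, 0.25 and 0.212). The hepatocyte call was lost with quantile normalization (adjusted p = 0.991), where the direction of the test turned but the median did not, and with cyclic loess (adjusted p = 0.228). In limma 1428 genes passed, 323 higher and 1105 lower at 11 weeks, 838 of them at least 2-fold. Of those at least 2-fold, 156 were higher and 682 lower. The size of the excess among all calls depends on the model: with the replicate number as a block 48.6% of calls were higher, against 22.6%. More genes passed with the block, while all 1428 stayed called in the same direction. The count came to 591 or 588 without C57BL/6J replicate 1 or 2 at 4 weeks, 461 without either C57BL/6J array at 11 weeks, 667 with normexp and 700 with no filter. The call of Olfr987 was lost without any of these 4 arrays (adjusted p = 0.0613 to 0.144) and under normexp (adjusted p = 0.151) or no filter (adjusted p = 0.0554). Normexp also ended the call of Rpl39l (adjusted p = 0.0502), and it brought Cfd to 3.37, Akr1c18 to -2.86, Slc22a26 to -3.24, Oas2 to -1.32, Gzma to -1.685 and Gzmb to -1.60, all still called.

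Between the same ages, KKAy livers had a fall of cell division and female-biased genes and higher endoplasmic reticulum stress genes, by list calls that held with an estimated correlation. By camera, male-biased and cholesterol synthesis genes were also shifted up and fatty acid oxidation genes down, and these calls were lost with an estimated correlation (adjusted p = 0.0713, 0.42 and 0.142). Of 26 male-biased genes 19 were higher (20 higher and 1 lower adjusted over the list alone), with a median of 1.38 and camera adjusted p = 1.12e-13, and adjusted p = 0.0713 with an estimated correlation. Hsd3b5, a male-specific steroid dehydrogenase gene of mouse liver on chromosome 3, rose by 5.23 (SE 0.11), its paralog Hsd3b4, which is not on the list, by 5.20 (SE 0.38), and Nox4 by 4.91 (SE 0.13). Cross-hybridization between the Hsd3b genes is possible. Moxd1 was at least 21.1-fold higher. Of 28 female-biased genes 19 were lower and 1 higher (19 and 1 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.0292). Cyp39a1 fell by 5.33 (SE 0.11) and Cyp2b9 by 4.95 (SE 0.14), and A1bg, Hao2 and the sulfotransferase gene Sult3a1 were at least 30.1-fold, 31.8-fold and 20.3-fold lower. Sult2a2 was at least 465-fold lower on its brightest probe, while its second probe gave -3.17.

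Of 26 endoplasmic reticulum stress genes 16 were higher and none lower (19 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.0292). Sdf2l1 rose by 2.50 (SE 0.10) and Derl3 by 3.14 (SE 0.13). Of 25 cholesterol genes 8 were higher and 1 lower (8 and 1 adjusted over the list alone), and of 35 fatty acid oxidation genes 10 were lower (14 adjusted over the list alone). Of 27 acute phase genes 10 were higher and 3 lower (12 and 3 adjusted over the list alone). Camera called these 3 lists (adjusted p = 0.0011, 0.000735 and 0.00356), and none held with an estimated correlation (adjusted p = 0.42, 0.142 and 0.344). The acute phase call was also lost with quantile normalization (adjusted p = 0.202) and cyclic loess (adjusted p = 0.0619). Among 26 triglyceride and lipid droplet genes 6 were higher and 7 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.543). Lpin1, a phosphatidate phosphatase, fell by 2.74 (SE 0.10), and Fitm1, a gene of lipid droplet formation, rose by 2.65 (SE 0.12). Among 47 xenobiotic metabolism genes 11 were higher and 14 lower (17 and 15 adjusted over the list alone; camera adjusted p = 0.877), and Gsta2, a glutathione transferase with close paralogs, rose by 3.21 (SE 0.19). The median of that list was 0.19 and its mean -0.18.

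Of 37 cell cycle genes 28 were lower (28 adjusted over the list alone), with Ccna2 down by -3.28 (SE 0.10) and Mki67 by -3.06 (SE 0.10), and of 15 fetal genes 6 were lower and 1 higher (8 and 1 adjusted over the list alone), with Igf2bp3 at least 34.7-fold lower. Both calls held with an estimated correlation (adjusted p = 0.0292 and 0.0469). Among cell type markers, 15 of 26 of Kupffer cells and macrophages were lower and 1 higher (16 and 1 adjusted over the list alone), with the scavenger receptor Marco at -4.89 (SE 0.36) and Gpnmb at least 3.21-fold lower. Of the stellate cell markers 15 of 26 were lower and 1 higher (18 and 2 adjusted over the list alone), with Col3a1 at -2.03 (SE 0.10) and Mmp2 at -1.99 (SE 0.13), and 6 of 20 endothelial markers were lower (7 adjusted over the list alone). These 3 calls held with an estimated correlation (adjusted p = 0.0292, 0.0292 and 0.0391). Of 22 lymphocyte markers 12 were lower and 1 higher (14 and 1 adjusted over the list alone), and of 33 interferon genes 8 were lower and 1 higher (10 and 2 adjusted over the list alone), with camera adjusted p = 0.000116 and 0.00956, and adjusted p = 0.344 and 0.309 with an estimated correlation. Normexp ended the lymphocyte call (adjusted p = 0.0526). Cfd was at least 24.1-fold higher, Adh6-ps1 18.2-fold and Olfr631 9.67-fold at the least. With normexp all 10 bounded genes lay below their bounds, at 1.63-fold (Gpnmb) to 105-fold (Sult2a2), and Mmp2 came to -0.67, all still called in the same direction. The agouti gene a did not pass (-0.26, SE 0.40, adjusted p = 0.719), and Raly fell by 0.54 (SE 0.14, adjusted p = 0.0452). This call was lost without any 1 of the 8 arrays (adjusted p = 0.0615 to 0.192), from the 4 arrays alone (adjusted p = 0.164) and with no filter (adjusted p = 0.144).

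In limma 3176 genes passed in KKAy, 1346 higher and 1830 lower, 1287 of them at least 2-fold. The count came to 1365 or 1341 without KKAy replicate 1 or 2 at 4 weeks, 1852 or 1874 without KKAy replicate 1 or 2 at 11 weeks, 1921 without either C57BL/6J array at 11 weeks, 1868 with normexp, 1463 with no filter and 742 from the 4 arrays alone. With spike-in scaling 19.4% of calls were higher at 11 weeks, against 42.4%, and the median of all genes was -0.19. Of 916 genes called in both strains, 194 rose in both and 666 fell in both, against 25.5 and 118.6 for independent lists, and 56 went opposite ways, against 121.9. Here too the lists share 1 estimate of the spread per gene, and age goes with slide in both strains.

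The interaction asked which genes changed with age differently in the 2 strains. The interaction passed the threshold above 0 in 8 and below 0 in none of 26 male-biased genes (8 and 1 adjusted over the list alone). It passed below 0 in 10 and above 0 in 2 of 28 female-biased genes (14 and 4 adjusted over the list alone). Camera called both sex-biased lists (adjusted p = 2.79e-08 and 2.93e-06), and neither was called with an estimated correlation (adjusted p = 0.213 and 0.0769). Hsd3b5 had an interaction of 4.87 (SE 0.16, adjusted p = 0.000572) and Keg1, an acyltransferase-like gene, of 3.09 (SE 0.15, adjusted p = 0.0018). Cyp39a1 stood at -4.87 (SE 0.15), Cyp2b9 at -4.50 (SE 0.20) and Cyp2b10 at -4.60 (SE 0.39), the latter 2 also members of the xenobiotic list. In that list 2 genes passed above 0 and 7 below (7 and 10 adjusted over the list alone, camera adjusted p = 0.985).

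The interaction passed the threshold above 0 in 4 of 26 endoplasmic reticulum stress genes (13 adjusted over the list alone) and in 3 of 25 cholesterol genes (6 adjusted over the list alone). It passed below 0 in 4 of 35 fatty acid oxidation genes (7 adjusted over the list alone). Camera adjusted p = 4.9e-10, 0.00107 and 1.41e-06 for the 3 lists, and with an estimated correlation adjusted p = 0.0769, 0.43 and 0.129. Past the threshold, the interaction was above 0 in 8 and below 0 in 1 of 33 interferon genes (12 and 1 adjusted over the list alone), with Cxcl9 at 1.97 (SE 0.19) but Usp18 at -1.81 (SE 0.15). It passed above 0 in 6 of 19 MHC genes (8 above and 1 below adjusted over the list alone). Beside them stood Kupffer cell and lymphocyte markers, which passed above 0 in 3 and below 0 in 1 of 26, and above 0 in 2 of 22 (8 and 3, and 3, adjusted over the list alone). Camera called these 4 lists (adjusted p = 7.62e-07, 7.62e-07, 0.0145 and 0.00038), and none held with an estimated correlation (adjusted p = 0.129, 0.231, 0.204 and 0.389). The Kupffer cell call was lost without KKAy replicate 2 at 4 weeks (adjusted p = 0.0568) or KKAy replicate 1 at 11 weeks (adjusted p = 0.0776). Neutrophil markers passed above 0 in 1 of 9 (2 adjusted over the list alone), and exocrine pancreas and gut markers in 1 of 10 (4 adjusted over the list alone). Camera called the neutrophil and exocrine lists as well (adjusted p = 0.0459 and 0.0286), but not with an estimated correlation (adjusted p = 0.231 and 0.459). Leaving out 1 array ended the neutrophil call for C57BL/6J replicate 2 at 4 weeks (adjusted p = 0.076) and at 11 weeks (0.083), KKAy replicate 2 at 4 weeks (0.0966) and KKAy replicate 1 at 11 weeks (0.147), and the exocrine call for C57BL/6J replicate 2 (0.168) and KKAy replicate 1 (0.0938) at 4 weeks. Normexp (adjusted p = 0.143 for both), no filter (0.135 for both), cyclic loess for the neutrophil list (0.0532) and probes above background on all arrays for the exocrine list (0.376) did so too. With fry the interaction calls of cholesterol genes (adjusted p = 0.0867), lymphocyte markers (0.0508) and exocrine markers (0.142) were lost.

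The largest interactions above 0 besides Hsd3b5 were Ppp1r42, at 5.71 (SE 0.45), Akr1c18, at 4.95 (SE 0.28), and Hsd3b4, at 4.84 (SE 0.54). The levels of Hsd3b4 followed those of its paralog Hsd3b5 over the groups, so the probes of these genes may not give separate signals. Below 0 were Sult2a2, at -6.96 (SE 1.08), Obp2a, at -5.63 (SE 0.63), Shbg, which encodes sex hormone-binding globulin, at -5.25 (SE 0.57), and Acot5, at -5.13 (SE 0.30). Each of the 4 was below background in at least 1 group, so these values depend on dim signals, and the second probe of Sult2a2 gave -3.30. The agouti genes did not pass: a stood at -0.44 (adjusted p = 0.81) and Raly at -0.53 (adjusted p = 0.237). In limma 650 genes passed, 351 above 0 and 299 below. The count came to 163 or 194 without C57BL/6J replicate 1 or 2 at 4 weeks, 62 or 82 without C57BL/6J replicate 1 or 2 at 11 weeks, 185 or 174 without KKAy replicate 1 or 2 at 4 weeks and 295 or 248 without KKAy replicate 1 or 2 at 11 weeks. It came to 321 with normexp, 142 with no filter and 416 with spike-in scaling, where 36.1% of calls were above 0 against 54% and the median of all genes was -0.21. Leaving out either C57BL/6J array at 11 weeks also ended the calls of Hsd3b4 (adjusted p = 0.0709 and 0.0633), Obp2a (0.0727 and 0.0719), Shbg (0.0588 and 0.0733), Usp18 (0.0504 and 0.0527) and Cxcl9 (0.0576 and 0.0539). Leaving out replicate 1 of that group ended that of Cyp2b10 (0.0504), leaving out KKAy replicate 1 at 4 weeks that of Shbg (0.0519), and leaving out any 1 of the 6 arrays other than those of KKAy at 11 weeks that of Sult2a2 (0.0981 to 0.133). Normexp brought Obp2a to -1.965 and Shbg to -1.525 and ended their calls (adjusted p = 0.0601 and 0.115), and Ppp1r42, Akr1c18 and Acot5 came to 3.56, 2.70 and -1.94, still called, so the size and order of these interactions depend on the background correction. Testing all probes ended the call of Sult2a2 (0.0931).

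**Figure D2:**
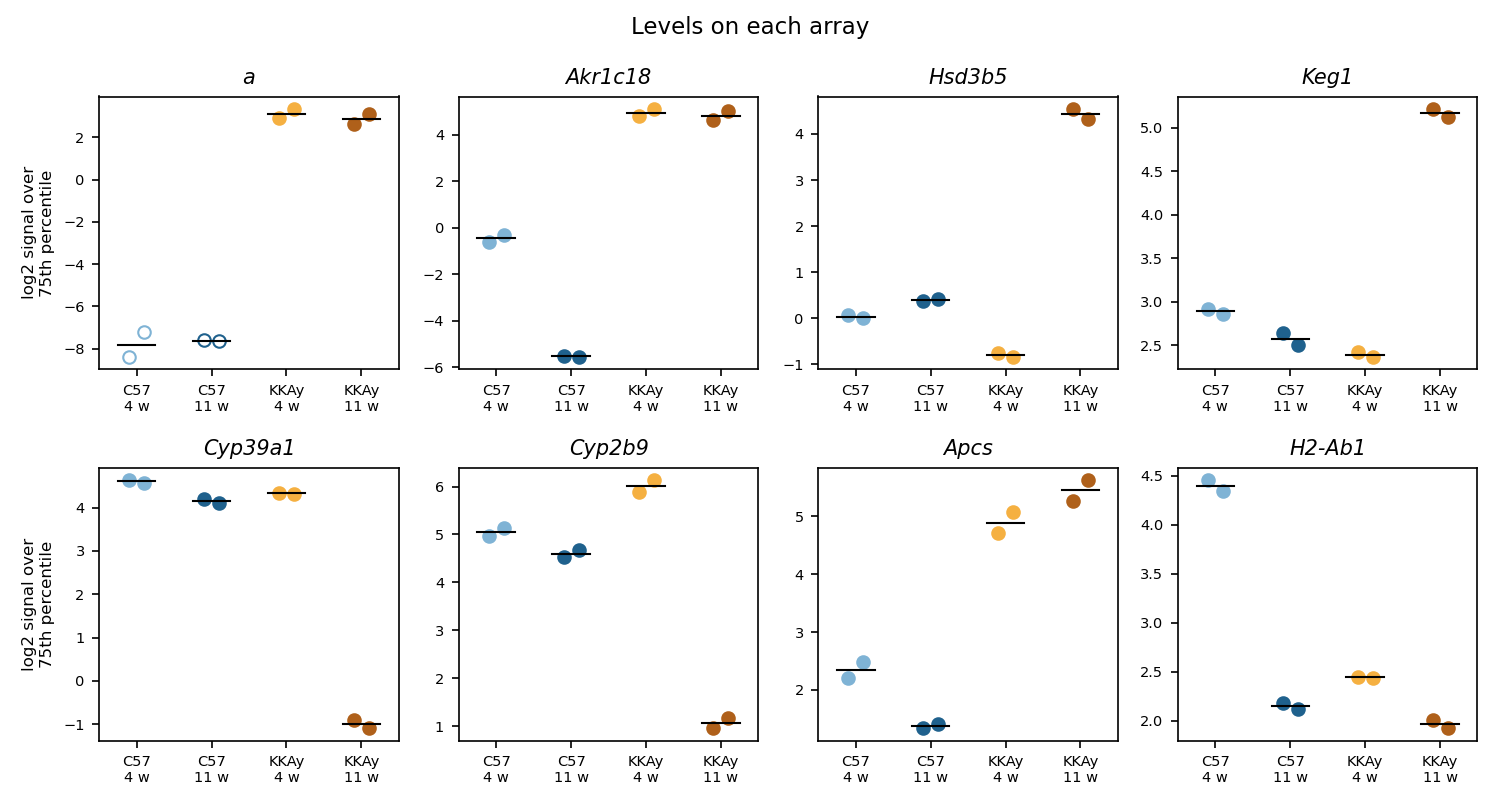
Level of 8 named genes on each of the 8 arrays, as log2 processed signal relative to the array's 75th percentile (vertical axes, each with its own range), by strain and age; points are arrays, open points are not well above background and bars are group means. Hsd3b5 and Keg1 are high, and Cyp39a1 and Cyp2b9 low, on both KKAy arrays at 11 weeks.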

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

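For the patterns weighed here, the tests of the sex of the mice, of paralogs, of the fasting response and of the share of hepatocytes were chosen only after the results they bear on were seen, and the paralog test of the male-biased genes alone was added after the joint test had been read, as was its narrower form after that.

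The difference between the strains in how genes changed with age was itself tested, and 650 genes passed. Among the 81 genes named, 46 passed, 27 with an interaction above 0 and 19 below. Most of these genes were named for large or low-p changes on the same arrays, some for the interaction itself. A share above that of all genes (650 of 17049) was therefore built in. Above 0 on the log2 scale were Ppp1r42 (5.71), Akr1c18 (4.95), Hsd3b5 (4.87), Hsd3b4 (4.84), Olfr631 (4.81), Adh6-ps1 (4.51), Derl3 (4.01), Moxd1 (3.62), Keg1 (3.09), Slc22a29 (2.64), Nox4 (2.55), Gzma (2.42), Sdf2l1 (2.34), Gsta2 (2.31), Elovl3 (2.29), Socs2 (2), Cxcl9 (1.97), Fitm1 (1.92), H2-Ab1 and H2-Eb1 (1.77 each), Irf7 (1.68), Apcs (1.53), Oas2 (1.40), Oasl2 (1.13), Mpeg1 (1.02), Col3a1 (1.01) and Hamp2 (0.79). Below 0 were Sult2a2 (-6.96), Obp2a (-5.63), Shbg (-5.25), Acot5 (-5.13), Cyp39a1 (-4.87), Rpl39l (-4.70), Cyp2b10 (-4.60), Cyp2b9 (-4.50), A1bg (-3.52), Marco (-3.11), Hnf4aos (-2.53), Sult3a1 (-2.49), Igfbp2 (-2.28), Ehhadh (-2), Lpin1 (-1.99), Acot2 (-1.83), Usp18 (-1.81), Cdh15 (-1.47) and Cyp1b1 (-1.12). A1bg, Acot5, Adh6-ps1, Gzma, Hnf4aos, Moxd1, Obp2a, Olfr631, Rpl39l, Shbg, Slc22a29, Sult2a2 and Sult3a1 were not well above background on either array of at least 1 group, so the floor of the signal bears on their values and ranks. With normexp Obp2a came to -1.965 and Shbg to -1.525, and neither was called. The same test over lists gave 11 called shifts by camera, none of them called with an estimated correlation (adjusted p = 0.0769 to 0.459), with median interactions of 0.80 for the interferon response, 0.77 for endoplasmic reticulum stress, 0.66 for male-biased genes, 0.43 for lymphocyte markers, 0.40 for MHC genes, 0.38 for Kupffer cell and macrophage markers, 0.37 for neutrophil markers, 0.36 for exocrine pancreas and gut markers, 0.34 for cholesterol synthesis, -0.35 for fatty acid oxidation and -1.07 for female-biased genes.

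The interaction passed the threshold above 0 in 8 of 26 male-biased genes and below 0 in 10 of 28 female-biased genes, with 2 of the latter passing above 0. Camera called both lists, and neither was called with an estimated correlation (adjusted p = 0.213 and 0.0769). Arrays from mice of different sex are argued against, since all 4 Y-linked genes were well above background on 8 of 8 arrays and the probes of Xist on 0. By these genes all 8 arrays read as male. Hybridization between paralogs cannot be told apart: 9 male-biased members outside the families first listed had a median interaction of 1.779 (95% bootstrap interval 0.237 to 3.09), but without Elovl3, Nudt7, Nox4 and Keg1, which have related genes too, the other 5 had 0.556 (-0.096 to 3.62), and male- and female-biased members outside families differed by 1.51 (-1.72 to 4.25). A weaker response to the overnight fast in KKAy at 11 weeks may contribute: the PPAR alpha list had a median interaction of -0.352 (-0.5 to -0.265), and with no fed mice the 2 cannot be told apart. A difference between the strains in maturation, or in diabetes at 11 weeks, stays open and untested, as does the position on the slide, which goes with strain.

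At 4 weeks 21 of 33 interferon, 12 of 19 MHC, 16 of 26 macrophage and 13 of 22 lymphocyte genes were lower in KKAy; camera called the 4 lists, and none with an estimated correlation (adjusted p = 0.0682, 0.25, 0.0682 and 0.25). The medians of 57 endothelial, stellate and bile duct markers (-0.105) and 48 lymphocyte and macrophage markers (-0.84) lay 0.735 apart (0.596 to 1). That interval comes from resampling markers as if independent, and leaves out the spread between samples. The gap argues only against a lower share of hepatocytes in the C57BL/6J samples of that age with all other cell types raised alike. A lower share through more immune cells alone would give the same gap and was not tested. A single array is argued against as well, since the interferon list had medians of -1.173 and -1.197 with either C57BL/6J array left out. An immune response in both C57BL/6J samples, a strain difference and the position on the slide remain possible explanations that were not tested.

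Genes called at both ages were taken here if their probe was well above background on all 4 arrays of the brighter strain. Of these, 55 were at least 8-fold lower in KKAy at both ages and 38 at least 8-fold higher. A sequence difference under the probe in KKAy could lower the signal with no change of transcript. Among genes with a second probe, that probe went along in 4 of 5 lower genes (80%) and in 7 of 9 higher genes (77.8%), a difference of 2.22 percentage points (-48.9 to 44.4; two-sided Fisher's exact p = 1). With so few second probes, lower transcript and poorer hybridization cannot be told apart for these genes. Thumpd1, Zfp874a and Camk2b are among them, with 1 probe each past the filter on dim probes.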

How the results depend on the processing

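Cyclic loess and spike-in scaling were chosen only after the data were seen; the other alternatives were planned. Of 130 named gene results 12 gained or lost their call under some alternative and 0 turned direction. Most of these were chosen as the largest or lowest-p changes of the main fit, so their stability does not extend to genes in general. A smaller fold was not counted as a change, and with normexp every fold given as a bound lay below it. On probes above background on all arrays only 78 named gene results could be compared. Of 55 list results the direction of the set test turned in 2. The median of the female-biased list at 11 weeks also went from -1.005 to 0.0507 with normexp and to 0.0142 on probes above background on all arrays, where the direction of camera did not turn. Normexp gave 2356 genes for strain at 11 weeks, 667 for age in C57BL/6J, 1868 for age in KKAy, 321 for the interaction and 981 strain differences at both ages; the cause was not tested. With no filter, which tests 27596 genes, 1505, 2126, 700, 1463 and 142 genes passed in the 5 comparisons and 900 at both ages. From only the 4 arrays of a comparison, which leaves fewer samples, 1405 and 2121 genes passed for strain at 4 and 11 weeks and 742 for age in KKAy. Spike-in scaling gave 416 genes for the interaction; the 7 spike-in probes lay at medians of -0.35, -0.142, -0.02, 0.193 and 0.203 relative to the percentile in the 5 comparisons, and the cause was not tested. Over the arrays left out in turn, where the lone array of a group is assumed to vary like the other groups, counts ran from 1317 to 2588 for strain at 4 weeks, 1474 to 3070 at 11 weeks, 461 to 1330 for age in C57BL/6J, 1341 to 2399 in KKAy, 62 to 295 for the interaction and 830 to 1313 at both ages. Camera called 55 list shifts, 12 with an estimated correlation, and fry, which does not compare a list with other genes, 88. The correlation was estimated from the fit without the replicate block, whose residuals hold the shared deviations of same-numbered arrays. Whether these deviations raised the estimates was not tested, so a call lost in this way does not by itself show a weak list shift. In the age difference of C57BL/6J the direction of camera turned for the hepatocyte list under quantile normalization, where its median came to 0.000639 and did not go below 0 (adjusted p = 0.991), and the median of the adipose list turned on probes above background on all arrays (-0.0675); the cause was not tested. With the replicate number as a block, 7473, 9367, 5770, 9100 and 5288 genes passed in the 5 comparisons and 4655 at both ages. Every gene called without the block stayed called, in the same direction, and in the age difference of C57BL/6J 48.6% of calls were higher, against 22.6% without it. Of the named gene results that of Raly in the interaction came to pass (adjusted p = 0.028). List calls not made under the block were those of erythroid markers at 4 weeks (adjusted p = 0.0504), female-biased genes (0.082) and neutrophil markers (0.0642) at 11 weeks, adipose markers with age in C57BL/6J (0.361) and exocrine markers in the interaction (0.135). Deviations of replicate 1 correlated at 0.53 to 0.676 over the 6 pairs of groups, so same-numbered arrays deviate together, and replicate 1 was the brighter array of each group. There are 2 numbers and no label says what a number marks, so the block was not taken as part of the design. A slide block was not run: the design with slide has 5 columns and rank 4 for age, and both strains lie on each slide, so the strain differences are already within a slide. Dim signal limits the comparisons, as 56.3% to 66.7% of spots were well above background.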

Other observations

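The tests on genes below are those of the main comparisons; the genes themselves were chosen only after their values were seen. Among triglyceride and lipid droplet genes at 11 weeks, 6 were higher and 5 lower in KKAy (8 and 8 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.994). Cidea, a lipid droplet protein gene, was higher by 3.92 (SE 0.34, adjusted p = 0.00104), Mogat1, an acyltransferase of triglyceride synthesis, by 3.61 (SE 0.33, adjusted p = 0.00121) and the fatty acid transporter gene Cd36 by 1.78 (SE 0.09, adjusted p = 0.000204), while Cidec was lower by -3.58 (SE 0.21, adjusted p = 0.000279) and the lipase gene Pnpla2 by -1.42 (SE 0.09, adjusted p = 0.000368). The interaction passed for Cidea (3.25, adjusted p = 0.0261), Cidec (-4.16, adjusted p = 0.00342), Cd36 (1.70, adjusted p = 0.00444) and Pnpla2 (-1.42, adjusted p = 0.00682). Scd1, a fatty acid desaturase gene, was lower in KKAy by -0.92 at 4 weeks and higher by 1.48 at 11 weeks, and its interaction passed (2.40, SE 0.19, adjusted p = 0.00452).

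Among bile acid genes at 11 weeks 5 were higher and 6 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.821). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was lower in KKAy by -2.44 (SE 0.10, adjusted p = 0.000108), and Nr0b2, which encodes a repressor of that gene, was lower at 4 weeks by -1.05 and higher at 11 weeks by 0.91, with an interaction of 1.97 (adjusted p = 0.00787). In the clock list, Dbp, an output gene of the circadian clock, was higher in KKAy by 1.95 at 4 weeks and by 3.07 at 11 weeks (adjusted p = 0.002 and 0.000346), and the hour of sampling is not given in the sources used here. Of 37 genes of mitochondrial oxidative phosphorylation 0 passed in limma in either strain comparison (camera adjusted p = 0.867 and 0.254), with medians of 0.03 and 0.11.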
